A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

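The authors deposited a table per library that gives a read count for each codon of each open reading frame. The values were read as raw counts because they were whole numbers with a different sum in each library. According to the submitters' processing notes, reads were called with CASAVA 1.8, trimmed with cutadapt 1.4.2 and aligned with Bowtie 1.0.0 to the sacCer3 and R64 builds. The handling of reads with several alignments, the assignment of a read to a codon and the strand filter are not given in the sources used here. Depth ran from 866435 to 130699138 reads per library. Sequence was taken from the codons written in the tables, and 7 flanking codons on each side of a reading frame were left out of gene totals.

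Groups, comparisons and the alternatives were chosen before the data were examined, and 5 more alternatives were added later. Gene totals of all 22 libraries were fitted together with edgeR quasi-likelihood, robust dispersion and TMM factors, 11 group means and contrasts of these. A gene was tested if its counts passed the edgeR expression filter, which left 5496. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM were scaled with the TMM factors, and RPM were reads over library totals without that scaling. The named genes were, for each comparison, the 8 called genes with the largest change in each direction among those with a mean log2 CPM of at least 4 and the same sign in the single libraries, up to 4 called members of each gene list, and a fixed set of actin, tubulin, ATP synthase, TRiC and Ssb genes and PMA1. Gene coordinates follow R64.

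Gene lists were fixed before testing and were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted with Benjamini-Hochberg over the 18 lists. Positions along the reading frame were compared over genes of at least 400 codons with at least 200 reads in every library. Windows of 30 codons that passed the edgeR expression filter were fitted in the same way, with the library sizes and factors of the gene fit. A filter of at least 20 reads on average was tried as an alternative. A window was enriched at an adjusted p under 0.05 and a log2 fold change of at least 1. An onset was the start of the first enriched window past codon 30, and onset differences were tested with a sign-flip permutation over genes. Occupancy over 30 codons from the onset and 30 codons before it in cycloheximide-free cells was tested against random positions of the same genes. Codon occupancy was the count at a codon over the mean of its gene and was tested with limma with trend and robust variance.

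The code was tested on simulated data made from the total libraries with known changes. At log2 changes of -2, -1, 1 and 2, the recovered shares were 96%, 86%, 94% and 98% for the TRiC design, with 19 false calls, or 9.22% of calls and so above the 5% aimed for. They were 92%, 84%, 90% and 92% for the Ssb design with 7 false calls (3.76%), and 96%, 84%, 74% and 98% for the mutant design with 10 (5.38%). In windows, 32% and 96% were recovered at log2 changes of 1 and 2 for TRiC, with 11 false calls (7.91%), and 40% and 99% for Ssb, with 10 (6.71%), both also above 5%.

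Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Alternatives tried were DESeq2, RLE scaling, capped codon counts, ends of reading frames left out, fits of only the libraries compared, a replicate block, single libraries left out and stricter thresholds.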

Results

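Ribosome-protected fragments of budding yeast were counted codon by codon in 22 libraries that form 11 groups of 2. The labels describe ribosomes bound to the chaperonin TRiC, ribosomes bound to the Hsp70 chaperone Ssb, and the total ribosomes of the same kind of lysate. TRiC and Ssb were each profiled with cycloheximide given at 100 µg/mL before fast filtration, and again with 5 mM puromycin in the lysis buffer, a drug that releases nascent chains. Further libraries held TRiC-bound and total ribosomes of a strain with substitutions in ATP2, which encodes the beta subunit of the mitochondrial ATP synthase. The last group held total ribosomes of wild-type cells of another strain that were not treated with cycloheximide. The labels of the puromycin libraries name no cycloheximide, so a puromycin comparison changed both drugs at once. TRiC, Ssb and mutant enrichments each had their own total libraries, and no library was shared among them. The edgeR and limma p-values measure the spread between these libraries. The labels do not say whether the 2 libraries of a group came from separate cultures. The sign-flip, exact sign and random-position tests take genes as their units. Genes are not replicates, so those tests describe these libraries only. Values after ± are standard errors of log2 fold changes, or the SD of 2 libraries where a mean is given.

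The tables covered 5796 open reading frames, of which 5795 began with ATG. Depth ran from 866435 reads in the second puromycin library of TRiC-bound ribosomes to 130699138 in the second total library of the mutant. The share of sense codons with any read ran from 6.98% to 71.3%. PDC1, a pyruvate decarboxylase, held the most reads in every library but the Ssb-bound pair, where SSB1 itself took 22.1% and 14.4%. The Ssb-bound libraries had composition factors of 0.582 and 0.691. Log counts of the paired libraries of a group correlated with r from 0.900 in puromycin TRiC-bound ribosomes to 0.999 in mutant total ribosomes. The first and second puromycin libraries of TRiC total ribosomes stood apart on the 8 mitochondrially encoded genes, with 4.59 and 345 RPM.

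Against their totals, Ssb-bound ribosomes were sparse over the first 60 codons of genes and were abundant past codon 100. TRiC-bound ribosomes leaned to the later parts of genes, weakly in wild type and more strongly in the ATP2 mutant. Over 296 genes, Ssb-bound libraries held 0.541 times the share of total libraries at codons 1 to 30 and 1.17 times between codons 100 and 200. Wild-type TRiC-bound libraries held 0.902 times the share at codons 1 to 30 and 1.09 times past codon 400, and mutant TRiC-bound libraries held 0.668 and 1.28 times. With at least 50 reads in every library, the wild-type bound and total ranges at codons 1 to 30 overlapped (0.901). As shares of gene reads, codons 1 to 30 held 5.69 ± 0.87% of Ssb-bound and 10.5 ± 0.42% of total reads. At codons 31 to 60 the shares were 4.13% and 7.58%, while TRiC totals held 5.35% and mutant totals 5.32% there. The Ssb depletion at codons 31 to 60 thus rests partly on denser Ssb totals. With puromycin the TRiC profile was nearly flat, at 1.07 and 1.01 times for the same ends of the gene, and the ranges of bound and total libraries overlapped in every codon range. That overlap ended at codons 61 to 100 with capped codon counts (0.953) and in genes of at least 600 codons (0.961), and between codons 30 and 200 with at least 50 reads (0.926 to 0.972), each with bound below total. The Ssb profile with puromycin kept a weaker form, 0.902 at codons 1 to 30 and 1.04 between codons 100 and 200, and its ranges did not overlap over codons 1 to 100 in any setting. With 2 libraries on each side an exact test cannot give a p below 0.333, so these ratios stand as sizes with ranges.

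**Figure D1:**
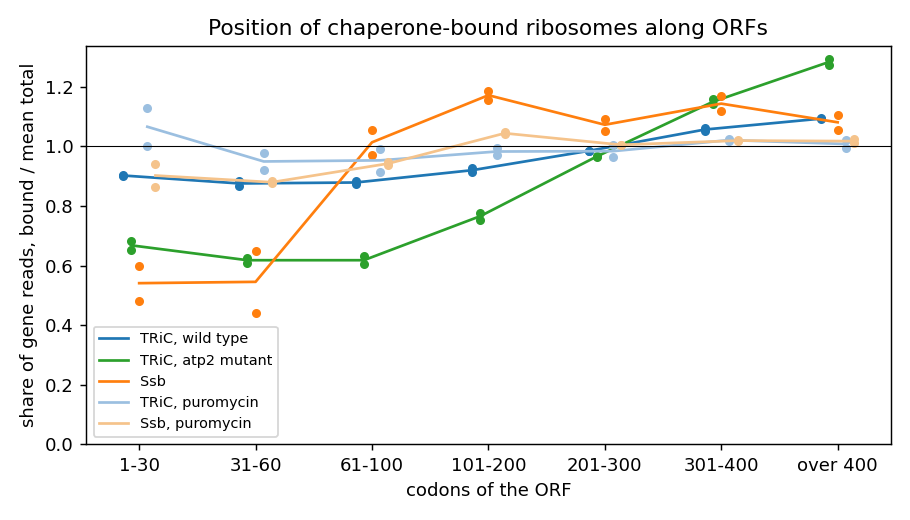
Share of gene reads per codon range in each chaperone-bound library divided by the mean share in its total libraries, drawn against codon range, with points for libraries and lines for group means. Ssb stood at 0.541 over codons 1 to 30 and mutant TRiC at 1.28 past codon 400.

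TRiC held ribosomes that were making some of its own subunits, beta-propeller proteins and tubulins. CCT3, a TRiC subunit (chromosome X, 407558 to 409162), was 4.14 ± 0.31 log2 units higher with TRiC than in total ribosomes (5323 ± 1029 against 302 ± 26.3 CPM, n = 2 each, edgeR adjusted p = 4.5e-07). PFS2, a WD-repeat factor of mRNA 3' end formation, stood at 3.28 ± 0.19, and CDC55, the propeller subunit of protein phosphatase 2A, at 3.09 ± 0.17. MTC5 and RTC1, propeller proteins of the SEA complex, stood at 3.28 ± 0.18 and 2.99 ± 0.21. The ubiquitin ligase activator CDC20 stood at 1.92 ± 0.11. The alpha-tubulins TUB3 and TUB1, whose reads may be shared between the paralogs, stood at 1.91 ± 0.13 and 1.37 ± 0.11. CCT5 and CCT8 were the other TRiC subunits called, at 2.51 ± 0.25 and 2.11 ± 0.18. TCP1, CCT2, CCT4, CCT6 and CCT7 stood between -0.02 and 0.07 and were not called. Why CCT3, CCT5 and CCT8 were enriched was not tested. RPO21, the largest subunit of RNA polymerase II, stood at 1.19 ± 0.17 (edgeR adjusted p = 1.5e-04).

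Actins and tubulins had 5 of 14 members higher with TRiC and 0 lower, 9 when adjusted over the list alone (camera adjusted p = 1.5e-18). That list kept an adjusted p = 3.6e-05 with an estimated correlation. Of 57 WD-repeat proteins 9 were higher and 10 over the list alone (camera adjusted p = 6.3e-15), with adjusted p = 0.00251 with an estimated correlation. Of 8 TRiC subunits 3 were higher, also 3 over the list alone (camera adjusted p = 1.9e-13), with adjusted p = 0.00765 with an estimated correlation. Ribosomal proteins leaned lower with 0 of 138 called (camera adjusted p = 7.8e-07), and that lean ended with adjusted p = 0.660 with an estimated correlation. Over the whole gene, actin ACT1 (0.24 ± 0.09, edgeR adjusted p = 0.480), beta-tubulin TUB2 (0.34 ± 0.10, adjusted p = 0.172) and ATP2 (-0.01 ± 0.12, adjusted p = 0.998) were not called.

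Among 5496 tested genes edgeR called 59 higher and 0 lower with TRiC at 5% false discovery, 29 of them at least 2-fold, and 435 had an unadjusted p under 0.05. DESeq2 called 83 higher and 6 lower, and a fit of only the libraries compared called 157 higher and 7 lower. Leaving out the second bound library left 37 calls, leaving out the first total library left 38, and leaving out the second total library left 34. THR1, a homoserine kinase (0.56 ± 0.13), was among the calls lost, while CCT3, PFS2, CDC55, TUB3 and TUB1 kept theirs.

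PFS2, MTC5, CDC55 and the alpha-tubulins lost much of their TRiC enrichment in the puromycin libraries, which also differed in cycloheximide. PFS2 lost 2.97 ± 0.31 log2 units of enrichment (edgeR adjusted p = 1.5e-05, n = 2 in each of the 4 groups), MTC5 lost 2.74 ± 0.27 and CDC55 lost 2.68 ± 0.25. TUB3 lost 1.69 ± 0.18 and TUB1 lost 1.39 ± 0.15. The subunits CCT3 and CCT8 lost 2.81 ± 0.40 and 1.71 ± 0.25, and their calls did not outlast every alternative. ACT1 lost 0.41 ± 0.13 and was not called (adjusted p = 0.302). Actins and tubulins had 3 of 14 members called, 6 over the list alone (camera adjusted p = 3.5e-08), with adjusted p = 0.00199 with an estimated correlation. WD-repeat proteins had 7 of 57, also 7 over the list alone (camera adjusted p = 3.3e-04), and ended with adjusted p = 0.132 with an estimated correlation. TRiC subunits had 3 of 8, also 3 over the list alone (camera adjusted p = 4.1e-07), and ended with adjusted p = 0.103 with an estimated correlation.

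For the loss of TRiC enrichment with puromycin, edgeR called 25 genes, all in the direction of a loss, with 540 at unadjusted p under 0.05, and DESeq2 called 39 losses and 7 gains. A fit of only the libraries compared called 5, which were PFS2, MTC5, CDC55, TUB3 and TUB1. Calls were 16 without the second TRiC total library, 48 and 54 without the first and second puromycin bound library, and 342 without the first puromycin total library, the one low in mitochondrially encoded reads, where 213 were losses and 129 gains. Within the puromycin libraries alone, TRiC-bound against total ribosomes gave 1 gene higher and 2 lower, with 921 at unadjusted p under 0.05.

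Ssb held ribosomes that were making Ssb itself, the mitochondrial enzyme LSC2 and many other proteins, such as FAS2 and TDH3. SSB1 (chromosome IV, 44065 to 45906) and its paralog SSB2 stood 6.39 ± 0.22 and 6.33 ± 0.22 log2 units higher with Ssb, and the nearly identical pair may share reads. LSC2, a subunit of the mitochondrial succinyl-CoA ligase, stood at 5.54 ± 0.24 (5528 ± 2489 against 119 ± 9.75 CPM, n = 2 each, edgeR adjusted p = 3.4e-12). PRE3, a catalytic proteasome subunit, stood at 1.79 ± 0.13, the fatty acid synthase FAS2 at 1.31 ± 0.15, the Ran GTPase GSP1 at 1.14 ± 0.11 and the co-repressor TUP1 at 1.01 ± 0.14. The paralogs RPL4A and RPL4B, ribosomal proteins, stood at 1.77 ± 0.16 and 1.73, and TDH3, a glycolytic glyceraldehyde phosphate dehydrogenase, at 1.06 ± 0.10. ATP2 stood at 0.51 ± 0.12 (edgeR adjusted p = 0.00282), and ACT1 at 0.09 ± 0.09 was not called (adjusted p = 0.476). Lower with Ssb were the prefoldin subunit GIM3 (-1.28 ± 0.25), the RNA polymerase subunit RPB4 (-1.23 ± 0.19), the proteasome subunit RPN9 (-0.99 ± 0.15) and the initiation factor SUI1 (-0.87 ± 0.18).

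Glycolytic enzymes had 11 of 19 members higher with Ssb and 0 lower, 12 over the list alone (camera adjusted p = 1.2e-06), and ended with adjusted p = 0.146 with an estimated correlation. WD-repeat proteins had 24 of 57 higher and 0 lower, 26 over the list alone (camera adjusted p = 1.2e-06), and ended with adjusted p = 0.120 with an estimated correlation. Enzymes of amino acid synthesis had 24 of 67 higher and 3 lower, 26 and 3 over the list alone (camera adjusted p = 1.5e-04), and ended with adjusted p = 0.695 with an estimated correlation. Respiratory and citric acid cycle proteins had 11 of 28 higher and 3 lower, the same over the list alone (camera adjusted p = 2.1e-04), and ended with adjusted p = 0.504 with an estimated correlation. Ribosomal proteins had 17 of 138 higher and 60 lower, 18 and 64 over the list alone (camera adjusted p = 1.5e-04), and membrane proteins of the secretory route had 3 of 72 higher and 26 lower, the same over the list alone (camera adjusted p = 0.0105). Both ended with adjusted p = 0.744 with an estimated correlation. Whether the ribosomal proteins were lower than other genes of their length was not tested. No camera call was made for actins and tubulins (3 of 14 higher), TRiC subunits (0 of 8), other chaperones (6 higher and 9 lower of 34), ATP synthase (2 and 6 of 17) or proteasome (7 and 9 of 31). The same held for tRNA synthetases (5 and 0 of 21), translation factors (9 and 3 of 39), RNA polymerases (7 and 5 of 24), small GTPases (6 and 4 of 23) and lipid enzymes (7 and 7 of 29). It also held for septins, kinesins and myosins (4 and 1 of 16) and for mitochondrially encoded genes (1 and 0 of 8).

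With Ssb 1883 of 5496 genes were called, 901 higher and 982 lower, and 272 at least 2-fold, with 2436 at unadjusted p under 0.05. DESeq2 called 2040. Leaving out the first bound library left 1069 and leaving out the first total library left 1029. With single-codon counts capped, 960 were higher and 608 lower. The short membrane protein PMP2 went from -1.27 ± 0.31 to 0.38 when the first 30 and last 10 codons were left out.

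SSB1, SSB2, LSC2 and enzymes such as FAS2 and TDH3 had less Ssb enrichment in the puromycin libraries. Part of it stayed for SSB1, SSB2 and LSC2. SSB1 and SSB2 lost 3.55 ± 0.26 and 3.46 ± 0.25 log2 units, and LSC2 lost 2.99 ± 0.28 (edgeR adjusted p = 3.8e-06, n = 2 in each of the 4 groups). PRE3 lost 1.61 ± 0.19, RPL4A lost 1.47 ± 0.22, FAS2 lost 1.12 ± 0.21, TDH3 lost 0.91 ± 0.14 and the pyruvate kinase CDC19 lost 0.81 ± 0.12. ATP2 was unmoved at -0.04 ± 0.17 (adjusted p = 0.938). With puromycin present, LSC2, SSB1 and SSB2 were still 2.54, 2.84 and 2.87 log2 units higher with Ssb than in total ribosomes, whereas FAS2 at 0.19 and TDH3 at 0.15 were not called (edgeR adjusted p = 0.552 for FAS2 and 0.483 for TDH3). Glycolytic enzymes had 6 of 19 losses, 9 over the list alone (camera adjusted p = 2.0e-07), and ended with adjusted p = 0.101 with an estimated correlation. WD-repeat proteins had 2 of 57, 12 over the list alone (camera adjusted p = 3.2e-07), and ended with adjusted p = 0.0841 with an estimated correlation. Amino acid enzymes had 4 of 67, 6 over the list alone (camera adjusted p = 4.5e-06), and ended with adjusted p = 0.598 with an estimated correlation.

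The loss of Ssb enrichment with puromycin was called for 76 genes and a gain for 24, 35 of them at least 2-fold, with 1089 at unadjusted p under 0.05, and DESeq2 called 382 genes. The number was 334 without the second Ssb-bound library, 50 and 52 without the first and second Ssb total library, 55 without either puromycin bound library, and 47 and 33 without the first and second puromycin total library. The losses and gains were 74 and 7 with capped codons, and 83 and 13 with the cycloheximide-free libraries outside the fit. A replicate block called more of both, and losses and gains were then closer in number. The gains of the ubiquitin protease UBP7 and the mitochondrial protease YTA12 (UBP7 -1.88 ± 0.37, YTA12 -1.26 ± 0.26) did not outlast the alternatives, and VPS54, a vesicle tethering protein, went from -1.0 ± 0.24 to 0.19 when the first 30 and last 10 codons were left out. Of 219 genes higher with Ssb in puromycin, 165 were also higher without it.

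CCT3, CDC55, PFS2 and the alpha-tubulins lay on the TRiC side, and SSB1, LSC2, FAS2 and TDH3 lay on the Ssb side. Set against its Ssb enrichment, the TRiC enrichment was higher for CCT3 by 4.0 ± 0.40 log2 units, for CDC55 by 3.25 ± 0.23, for PFS2 by 2.39 ± 0.26, for TUB3 by 1.35 ± 0.18 and for TUB1 by 0.89 ± 0.15 (edgeR adjusted p = 0.00109, n = 2 in each of the 4 groups). The Ssb side held SSB1 (-6.40 ± 0.27), SSB2 (-6.38 ± 0.27), LSC2 (-5.48 ± 0.30), RPL4A (-1.99 ± 0.22), PRE3 (-1.74 ± 0.19), FAS2 (-1.15 ± 0.21), TDH3 (-1.07 ± 0.14), CDC19 (-0.96 ± 0.12) and the Hsp70 nucleotide exchange factor SSE1 (-0.72 ± 0.14). ATP2 lay toward Ssb without a call (-0.52 ± 0.17, adjusted p = 0.0564), and ACT1 did not separate the chaperones (0.14 ± 0.13, adjusted p = 0.521). Glycolytic enzymes had 8 of 19 members toward Ssb and 0 toward TRiC, 11 over the list alone (camera adjusted p = 5.6e-07), and ended with adjusted p = 0.117 with an estimated correlation. Respiratory and citric acid cycle proteins had 7 of 28 toward Ssb, 8 over the list alone (camera adjusted p = 7.9e-06), and ended with adjusted p = 0.195 with an estimated correlation. Actins and tubulins had 4 of 14 toward TRiC, 7 over the list alone (camera adjusted p = 5.1e-04), and ended with adjusted p = 0.0605 with an estimated correlation. The chaperones overlapped more than they excluded each other, since 42 of the 59 TRiC genes were also higher with Ssb (9.67 expected at random) and 0 were lower (10.5 expected). Expected counts here and below treat all genes alike, although both enrichments rose with gene length (Spearman 0.327 for TRiC and 0.342 for Ssb). No expectation matched for length or read depth was made.

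In the comparison of TRiC with Ssb, 223 genes were called toward TRiC and 292 toward Ssb, 515 in all and 140 at least 2-fold, with 1394 at unadjusted p under 0.05, and DESeq2 called 722. The number was 241 without the second TRiC-bound library, 270 and 284 without the first and second TRiC total library, 292 and 781 without the first and second Ssb-bound library, and 235 and 335 without the first and second Ssb total library. With capped codons 102 lay toward TRiC and 250 toward Ssb.

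**Figure D2:**
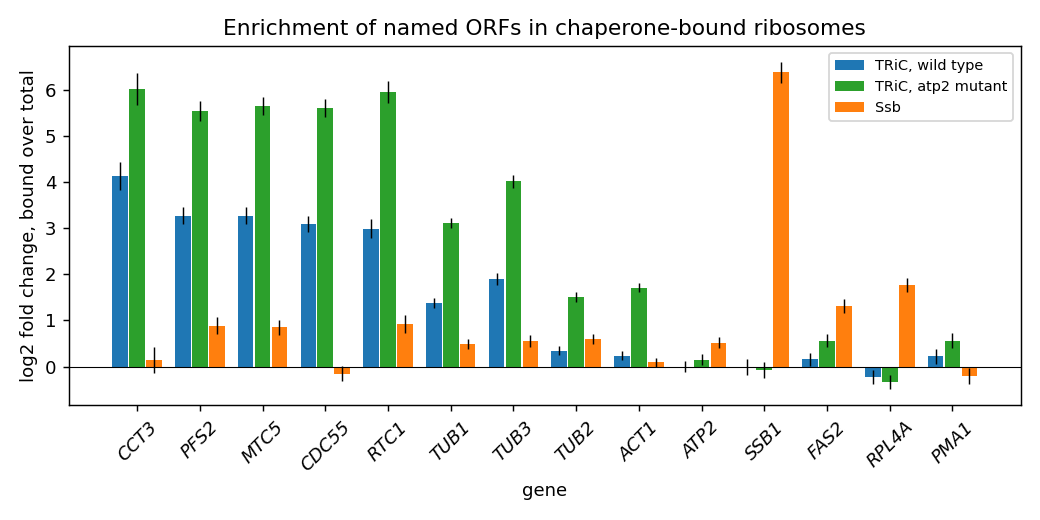
Log2 fold change of bound over total ribosomes for 14 genes with TRiC in wild type (blue), TRiC in the ATP2 mutant (green) and Ssb (orange), with bars as standard errors. CCT3 stood at 4.14, 6.03 and 0.14 in that order, and SSB1 was high with Ssb alone.

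Along single genes, TRiC arrived late on ACT1 and TUB2 although the whole-gene values were not called. ACT1 (chromosome VI, 53260 to 54696) stood at 1.66 ± 0.22 log2 units in codons 331 to 360 with wild-type TRiC (edgeR adjusted p = 3.1e-05 over all windows, n = 2 each), the only window of the gene to pass. With Ssb the only ACT1 window to pass was codons 361 to 375 (1.10, adjusted p = 0.00552). TUB2, beta-tubulin, passed with TRiC in codons 331 to 360 (1.13 ± 0.23, adjusted p = 0.0101) and with Ssb in codons 151 to 180 (1.52 ± 0.24). FAS1, the other fatty acid synthase subunit, passed in 0 of 68 windows with TRiC. With Ssb FAS1 passed in codons 901 to 930 and 1951 to 1980 (1.77 ± 0.23, adjusted p = 6.6e-06), and mutant TRiC passed in these windows as well (1.43 ± 0.22 in the latter). ATP2 passed in 0 of 17 windows with wild-type TRiC, and with Ssb it passed in codons 91 to 120 (1.58 ± 0.27, adjusted p = 3.5e-04) and 181 to 210. Of 83326 windows of 30 codons in 5377 genes, edgeR called 590 enriched with TRiC in 340 genes and 30 depleted, and 3693 enriched with Ssb in 1844 genes and 3762 depleted. Of 5104 first windows, 1585 were depleted with Ssb, with a median of -1.08. Enriched TRiC windows were 338 without the second bound library, 272 without the first total library and 185 without the second, and leaving out the first Ssb total library left 1279 enriched Ssb windows.

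Within the same gene, Ssb enrichment began earlier than wild-type TRiC enrichment. BLM10, a proteasome activator, first passed at codon 2071 with TRiC and at codon 61 with Ssb, the Ras regulator IRA1 at 2131 and 421, the ubiquitin ligase UBR1 at 1891 and 271, and the glucan synthase FKS1 at 1801 and 331. SEA4 of the SEA complex went the other way, at 511 with TRiC and 811 with Ssb, and so did ACT1 at 331 and 361. Of 288 genes with both onsets (116 expected at random), TRiC began later in 193, earlier in 10 and in the same window in 85, with a median of 120 codons (sign-flip permutation p = 1e-05, the smallest it can give). The size of the lag depended on how many windows each chaperone was allowed to pass. With the same number of windows, 589 for each, 84 genes had both onsets, and TRiC began later in 27, earlier in 12 and in the same window in 45 (exact sign test p = 0.0237). Their mean difference was 90.4 codons, against 242 for the 288 genes. Their median was tied at 0, so the permutation of the median carries no information there. With a log2 fold change of at least 2 asked for, the median was 0 over 63 genes. With mutant TRiC in place of wild type, 562 of 1210 genes were later, 250 earlier and 398 in the same window (exact sign test p = 2.1e-28), again with a median tied at 0. That call ended with the same number of windows for mutant TRiC and Ssb, where 25 of 72 genes were later, 16 earlier and 31 in the same window (exact sign test p = 0.211). IRA1, UBR1 and FKS1 had mutant TRiC onsets in the same windows as their Ssb onsets, and BLM10 had its mutant TRiC onset at codon 661. The mutant had 6419 enriched TRiC windows against 590 in wild type. Its onsets came before the wild-type ones in 231 of 338 genes and after them in 0. Mutant and wild-type TRiC onsets were not compared with an equal number of windows. Over the genes with both onsets the medians were codon 481 for wild-type TRiC and 271 for Ssb, and with the same number of windows they were 391 and 316.

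**Figure D3:**
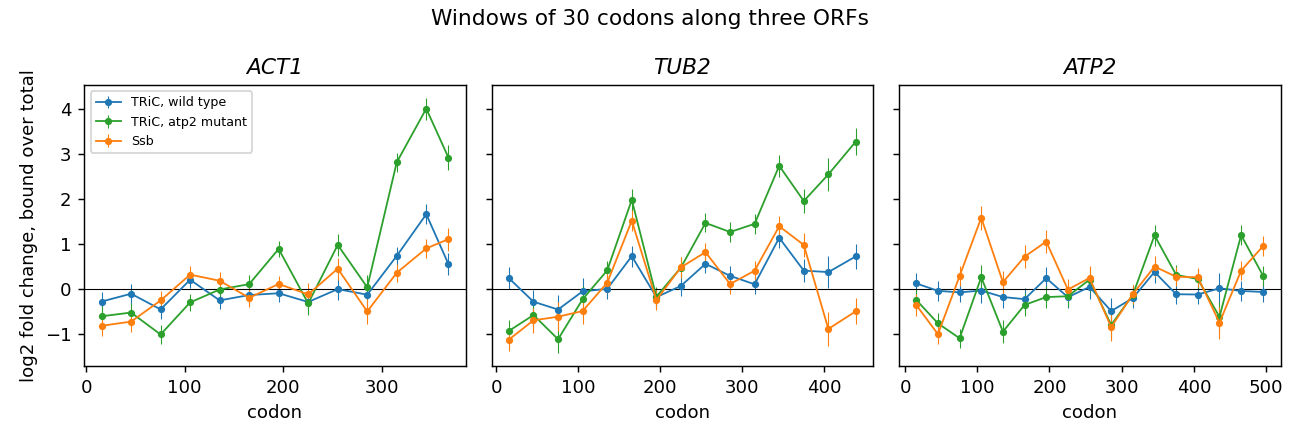
Log2 fold change of bound over total ribosomes in windows of 30 codons along ACT1, TUB2 and ATP2, drawn against codon, for wild-type TRiC (blue), mutant TRiC (green) and Ssb (orange), with bars as standard errors. On ACT1 wild-type TRiC reached 1.66 and mutant TRiC 4.02.

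In the ATP2 mutant, TRiC again held ribosomes on actins, tubulins and WD-repeat proteins, along with many more genes. CCT3 stood at 6.03 ± 0.34 log2 units (25710 ± 2371 against 394 ± 68.8 CPM, n = 2 each, edgeR adjusted p = 2.5e-09), MTC5 at 5.66 ± 0.19, CDC55 at 5.61 ± 0.19 and the deadenylase subunit PAN2 at 5.60 ± 0.30. TUB3 and TUB1 stood at 4.02 ± 0.14 and 3.12 ± 0.11, the actin-related protein ARP4 at 2.92 ± 0.14, ACT1 at 1.71 ± 0.10 and TUB2 at 1.51 ± 0.10. The vacuolar ATPase subunit STV1 stood at 3.45 ± 0.18, the class I myosin MYO5 at 1.61 ± 0.19 and the dynein heavy chain DYN1 at 1.41 ± 0.19. Lower with TRiC were the paralogs RPL1B (-1.39 ± 0.21) and RPL1A, the prefoldin subunits PFD1 (-1.15 ± 0.23) and GIM4 (-1.03 ± 0.19), the ATP synthase subunit ATP16 (-1.07 ± 0.14) and the elongation factor YEF3 (-0.73 ± 0.12). Genes of up to 200 codons were lower as a whole too, with medians given below. ATP2 itself was not called (0.14 ± 0.12, adjusted p = 0.347). Actins and tubulins had 13 of 14 members higher, the same over the list alone (camera adjusted p = 1.1e-31), with adjusted p = 1.8e-06 with an estimated correlation. WD-repeat proteins had 33 of 57 higher and 3 lower, the same over the list alone (camera adjusted p = 1.0e-17), with adjusted p = 0.00100 with an estimated correlation. Ribosomal proteins had 119 of 138 lower and 1 higher, 121 and 1 over the list alone (camera adjusted p = 2.0e-22), and ended with adjusted p = 0.164 with an estimated correlation. Chaperones other than TRiC, a list of Hsp70, Hsp90, prefoldin and further chaperone genes, had 23 of 34 lower and 1 higher, the same over the list alone (camera adjusted p = 1.4e-04), and ended with adjusted p = 0.221 with an estimated correlation. TRiC subunits (4 of 8 higher, 1 lower), ATP synthase (10 of 17 lower), proteasome (16 of 31 lower, 2 higher) and septins, kinesins and myosins (7 of 16 higher) passed with the preset correlation alone, with adjusted p = 0.176 or more with an estimated correlation.

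In mutant TRiC 2458 genes were called, 1262 higher and 1196 lower, and 569 at least 2-fold, with 2834 at unadjusted p under 0.05, and DESeq2 called 2543. A fit of only the libraries compared called 4056. Leaving out the second mutant bound library left 1569. All 59 genes higher with wild-type TRiC were also higher with mutant TRiC (13.5 expected at random), and across genes the mutant and wild-type enrichments correlated at r = 0.411. Longer genes had more enrichment in all 3 pulldowns, with Spearman 0.544 for mutant TRiC, 0.327 for wild-type TRiC and 0.342 for Ssb. The relation was weaker but present in the puromycin libraries, at 0.186 for TRiC and 0.263 for Ssb. With mutant TRiC, the median log2 fold change was -0.57 in the shortest length class and -0.58 in the next, which ends at 200 codons. PFD1, GIM4 and ATP16 are that short, with 109, 111 and 160 codons, but RPL1B has 217 and YEF3 1044. Whether these genes or the ribosomal proteins were lower than other genes of their length was not tested.

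Set against wild type, the mutant enrichment was larger for actins, tubulins and WD-repeat proteins. PAN2 gained 3.42 ± 0.36 log2 units (edgeR adjusted p = 9.1e-06, n = 2 in each of the 4 groups), CCT8 gained 3.12 ± 0.25, the coat protein SEC31 gained 2.91 ± 0.25 and STV1 gained 2.87 ± 0.24. TUB3 gained 2.11 ± 0.18, TUB1 gained 1.74 ± 0.15, ACT1 gained 1.48 ± 0.13 and TUB2 gained 1.17 ± 0.14. RPS6A, a ribosomal protein whose paralog may share its reads, stood at -1.18 ± 0.25, and the RNA polymerase III subunit RPC34 stood at -1.10 ± 0.24. ATP2 did not move (0.15 ± 0.17, adjusted p = 0.593). Actins and tubulins had 13 of 14 gains, the same over the list alone (camera adjusted p = 8.4e-30), with adjusted p = 3.2e-06 with an estimated correlation. WD-repeat proteins had 22 of 57 gains, 23 over the list alone (camera adjusted p = 1.6e-16), with adjusted p = 0.00161 with an estimated correlation. Ribosomal proteins had 73 of 138 losses, 99 over the list alone (camera adjusted p = 6.4e-23), and ended with adjusted p = 0.158 with an estimated correlation. TRiC subunits had 3 of 8 gains and 0 losses, 3 and 1 over the list alone (camera adjusted p = 0.00742), and ended with adjusted p = 0.341 with an estimated correlation. Of 812 genes called, 520 were higher and 292 lower in the mutant and 223 at least 2-fold, with 1649 at unadjusted p under 0.05, and DESeq2 called 1042. A fit of only the libraries compared called 2147. Calls were 474 and 434 without the first and second wild-type bound library, 443 and 451 without the wild-type totals, 503 and 241 without the mutant bound libraries, and 325 and 278 without the mutant totals. ACT1, TUB1, TUB2 and PAN2 kept theirs. Each strain had its own pulldown, so genotype and capture changed together.

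Total ribosomes of the mutant shifted toward glycolytic enzymes and held almost no reads on mitochondrially encoded genes. ENO1, an enolase, stood 1.26 ± 0.15 log2 units higher in mutant than in wild-type total ribosomes, the hexokinase HXK1 at 1.15 ± 0.17, the cytosolic aminotransferase BAT2 at 1.26 ± 0.14, the hypoxic eIF5A gene ANB1 at 2.06 ± 0.33 and the drug pump PDR15 at 1.88 ± 0.28 (edgeR adjusted p = 4.6e-04, n = 2 each). The mitochondrial aconitase ACO1 and chaperonin HSP60 stood at 0.94 ± 0.11 and 0.62 ± 0.10. Lower were the secreted protein CSS1 (-2.69 ± 0.24), the mitochondrial carrier ODC2 (-1.62 ± 0.24), the aromatic amino acid catabolism genes ARO10 (-1.20 ± 0.16) and ARO9 (-1.11 ± 0.17) and the transaminase ALT2 (-1.08 ± 0.14). ATP2 was not called (-0.19 ± 0.12, adjusted p = 0.515). Glycolytic enzymes had 6 of 19 higher, 15 over the list alone (camera adjusted p = 1.1e-16), with adjusted p = 0.0141 with an estimated correlation. Ribosomal proteins had 30 of 138 lower, 86 over the list alone (camera adjusted p = 5.7e-34), and ended with adjusted p = 0.0813 with an estimated correlation. ATP synthase proteins had 3 of 17 lower, 10 over the list alone (camera adjusted p = 6.6e-06), and ended with adjusted p = 0.231 with an estimated correlation.

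The 8 mitochondrially encoded genes had 3 lower, 6 over the list alone (camera adjusted p = 1.4e-09), and ended with adjusted p = 0.131 with an estimated correlation. They held 0.157 RPM in mutant total ribosomes (35 reads, 95% interval 0.109 to 0.219) and 31.2 in wild-type TRiC total ribosomes (2370 reads, 30.0 to 32.5). These intervals cover counting error only, since reads amplified by PCR are not independent molecules. The number of genes called between the totals was 87 higher and 76 lower, 163 in all and 38 at least 2-fold, with 830 at unadjusted p under 0.05, and DESeq2 called 318. A fit of only the libraries compared called 1243. Calls were 96 and 63 without the first and second wild-type total library, and 47 and 44 without the mutant ones, and CSS1, ENO1, BAT2 and ACO1 kept theirs.

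Along ATP2 itself, TRiC leaned in the mutant toward the end of the reading frame, as it did across genes, where the share at codons 61 to 100 was 0.879 of total in wild type and 0.618 in the mutant. Codons 451 to 480 gained 1.25 ± 0.31 log2 units of TRiC enrichment over wild type (edgeR adjusted p = 0.00664 over the 17 ATP2 windows, n = 2 in each of the 4 groups) and codons 61 to 90 stood at -1.02 ± 0.30 (adjusted p = 0.0187). Adjusted over all windows neither passed, with adjusted p = 0.0612 and 0.143. The window of codons 331 to 360, which holds the substituted residues, stood at 0.82 ± 0.34 and was not called (adjusted p = 0.118). Against its own totals, mutant TRiC passed on ATP2 in codons 331 to 360 and 451 to 480 (1.19 ± 0.22, adjusted p = 3.4e-04 over all windows). Ribosome occupancy of ATP2 in total ribosomes differed in 0 of 17 windows between mutant and wild type, in 1 with windows of 15 codons and in 3 of 17 when only the 8 libraries compared were fitted. The 2 ATP2 windows fell to 0 without the second wild-type bound library or the first wild-type total library, and to 1 without the second wild-type total library or any mutant library. With windows of 15 codons they fell to 0, and they rose when only the 8 libraries compared were fitted and with a replicate block.

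In the first cycloheximide-free library, ribosomes were slightly denser after a TRiC onset than before it. For 291 genes with a wild-type TRiC onset, the log2 occupancy after over before was 0.17 in that library, against -0.04 at random positions of the same genes (permutation p = 1e-05, the smallest it can give). In the second library it was 0.04 against -0.04 (permutation adjusted p = 0.0411), a call that ended with flanks of 15 codons (adjusted p = 0.115) and in genes with at least 5 reads per codon (adjusted p = 0.181). For 1616 genes with an Ssb onset it was 0.06 against -0.05 in the first library, which turned to -0.06 against -0.10 with flanks of 60 codons (permutation adjusted p = 0.00270). In the second library it was 0.02 against -0.05 (permutation adjusted p = 1.4e-04). That last call ended with flanks of 60 codons (-0.0694 against -0.0822 at random, adjusted p = 0.287) and in genes with at least 5 reads per codon (-0.0321 against -0.0495, adjusted p = 0.330). For 1703 genes with a mutant TRiC onset it was 0.16 against -0.05 in the first library. In the second library it was 0.07 against -0.04 over 1702 genes (permutation adjusted p = 1.5e-05), and these onsets passed in every setting tried, with adjusted p = 0.00346 at flanks of 15 codons. These libraries held total ribosomes only, so the occupancy was not that of chaperone-bound ribosomes. An onset also needs a window with enough reads to pass a count test, and the random positions were not matched for read density. The permutation therefore cannot tell a change in translation speed from easier calling of windows dense in reads.

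Cells without cycloheximide held more ribosomes on the arginine codons CGA and CGG and on tryptophan and histidine codons. The arginine codon CGA stood 2.03 ± 0.06 log2 units higher than in cycloheximide-treated totals (limma adjusted p = 1.6e-18 across 61 codons) and CGG at 1.75 ± 0.08, while the arginine codon CGC was not called (0.11 ± 0.11, adjusted p = 0.407). TGG, the tryptophan codon, stood at 1.04 and the histidine codon CAT at 0.80. Lower were the serine codon TCC (-0.82), the threonine codon ACC (-0.66) and the alanine codon GCC (-0.65). In all 21 codons were higher and 15 lower over 3266 genes, with 38 at unadjusted p under 0.05. The cycloheximide-free libraries also came from another strain, with a sucrose gradient and another removal of ribosomal RNA, and these changes cannot be told apart from the drug.

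**Figure D4:**
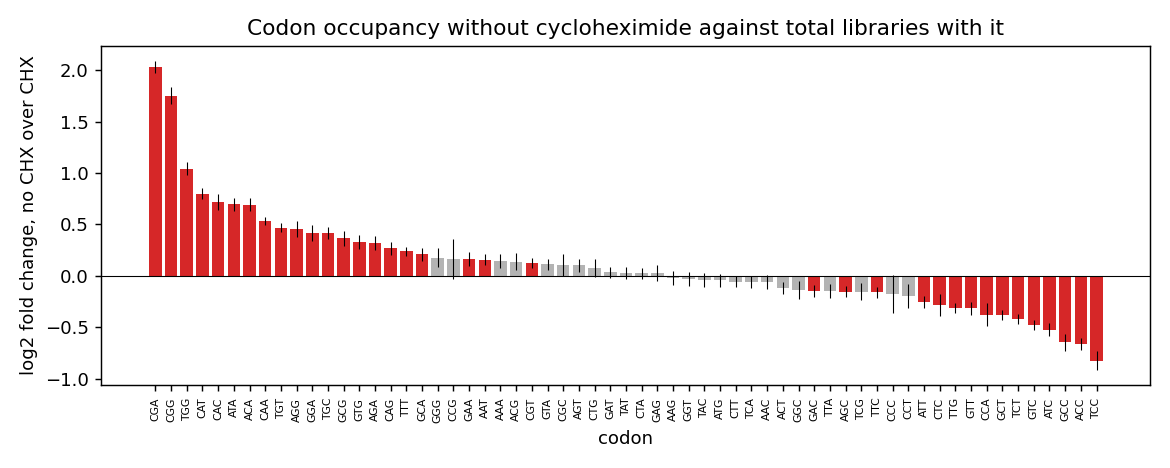
Log2 occupancy of the 61 sense codons in cycloheximide-free over cycloheximide-treated total ribosomes, with bars as standard errors and red for codons that passed. CGA reached 2.03 and TCC fell to -0.82.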

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

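The tests of explanations below were written down before their own values were seen, except the test of single-codon pileups, which was chosen only after the result was seen. Read positions and some fold changes were known before the mixture test was written. The results here were singled out because a tested difference between groups passed: 812 genes between mutant and wild-type TRiC enrichment, 25 for TRiC and 100 for Ssb between cells lysed with and without puromycin, and 515 between TRiC and Ssb enrichment, all by edgeR.

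TRiC held more genes in the ATP2 mutant than in wild type, with 1262 higher and 1196 lower in the mutant and 59 higher and 0 lower in wild type. For a lower share of TRiC-bound ribosomes in the wild-type bound libraries, wild type was taken as a mixture with a bound share of 0.325, set from read positions. Over the genes higher in the mutant the median log2 fold change was 0.31 predicted and 0.18 observed, and the median residual of -0.146 (median absolute deviation 0.17) lay just inside the bound of 0.15 set beforehand, which with predictions that small could hardly have excluded a mixture and leaves it open. Deeper sequencing of the mutant libraries did not account for the difference by the test set for it. Thinning them to 31722800 reads, the mean of the wild-type bound and total TRiC libraries, still gave 2411 genes, 1233 higher and 1178 lower. The wild-type bound libraries lay below that depth, at 28641929 and 22303678 reads. The share of codons with any read was not matched. For the mutations in ATP2 no value decides, since genotype and pulldown changed together, and 0 of the 59 wild-type genes had a lower call in the mutant.

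Ssb-bound ribosomes were very rich in SSB1, SSB2 and LSC2. For a pileup of reads on single codons, each codon count was capped at 20 times the gene mean. LSC2, SSB1 and SSB2 then stood at 5.64, 6.18 and 6.13 log2 units, against 5.54, 6.39 and 6.33 uncapped. Codons above that cap thus did not carry the enrichment. The bound set for this test could hardly be reached with such a cap, so the bound decides nothing. A milder pileup below the cap was not tested. For capture without an exposed nascent chain, LSC2, SSB1 and SSB2 stood at -0.77, -0.16 and -1.14 over codons 1 to 30. By the bound set beforehand that excluded such capture at the first codons. With puromycin, which releases nascent chains, the 3 genes were still 2.54, 2.84 and 2.87 log2 units higher with Ssb. Whether their chains had been released was not tested, so capture without a chain at later codons stays open. For all 3 genes the cause remains open.

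Short genes had fewer Ssb-bound reads than long ones. A larger part of a short gene lies in the first codons, where bound ribosomes were few, and leaving out codons 1 to 60 moved the difference between genes under 200 codons and longer ones from -0.42 to -0.24. By the bounds set beforehand that value cannot tell whether the first codons account for the lower reads on short genes.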

How the results depend on the processing

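Of the alternative values for named genes, 7829 kept direction and side of the threshold, 1026 fell short of it, 48 passed it and 2 reversed; of the main results 159 kept their value, 94 moved and 7 fell short. Alternatives chosen after seeing the data were CCT3, SSB1, SSB2 and LSC2 left out, the cycloheximide-free libraries left out, the replicate block for onsets, an equal number of windows, and mutant in place of wild-type TRiC for onsets. A library left alone in its group was assumed to vary like the others. The reversals were PMP2 with Ssb, from -1.27 to 0.38, and VPS54 for Ssb with puromycin, from -1.0 to 0.19, both with the first 30 and last 10 codons left out. For these changes and those below the cause was not tested. Depth was lowest, at 866435 reads, in the second puromycin TRiC-bound library.

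Genes called, by comparison. TRiC (59): DESeq2 89, only the libraries compared 164, at least 2-fold 29, leaving out single libraries 34 to 52. Ssb (1883): 1097 at a false discovery rate of 0.01, at least 2-fold 272, single libraries left out 1029 to 1864. TRiC with puromycin (25): DESeq2 46, only the libraries compared 5, single libraries left out 16 to 342. Ssb with puromycin (100): DESeq2 382, rate of 0.01 30, at least 2-fold 35, single libraries left out 33 to 334. TRiC against Ssb (515): rate of 0.01 153, at least 2-fold 140, single libraries left out 235 to 781. Mutant TRiC (2458): only the libraries compared 4056, at least 2-fold 569, single libraries left out 1569 to 1920. Mutant against wild-type TRiC (812): only the libraries compared 2147, capped codons 538, rate of 0.01 276, at least 2-fold 223, single libraries left out 241 to 503. Mutant against wild-type totals (163): DESeq2 318, only the libraries compared 1243, capped codons 98, rate of 0.01 72, at least 2-fold 38, single libraries left out 44 to 96.

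Enriched TRiC windows (590) were 281 at log2 of at least 2 and 185 to 503 with single libraries left out, and Ssb windows (3693) were 846 and 1279 to 3567. The onset median of 120 codons became 0 at log2 of at least 2, 0 with an equal number of windows (45 of 84 genes tied) and 0 with mutant TRiC (398 of 1210 tied), and 120 to 150 with single libraries left out. The 2 ATP2 windows were 0 with 15 codons, 1 with 60, 5 with only the 8 libraries compared, and 0 to 2 with single libraries left out. In totals the 0 ATP2 windows became 1 with 15 codons and 3 with only the 8 libraries. In the second cycloheximide-free library the TRiC value of 0.04 was 0.0638 with flanks of 15 codons and 0.0259 with at least 5 reads per codon, neither of them called, and the Ssb value of 0.02 was -0.0694 with flanks of 60 codons and -0.0321 with at least 5 reads per codon, neither of them called. Past codon 400, TRiC went from 1.09 to 1.06 and mutant TRiC from 1.28 to 1.21 in genes of at least 600 codons, and Ssb from 1.08 to 1.12 with at least 50 reads. Mutant TRiC at codons 1 to 30 went from 0.668 to 0.615 and 0.628 in these settings. Gene lists called, with the preset and then an estimated correlation, were 6 and 3 for TRiC, 6 and 0 for Ssb, 3 and 1 for TRiC with puromycin, 7 and 0 for Ssb with puromycin, 7 and 0 for TRiC against Ssb, 8 and 2 for mutant TRiC, 6 and 2 for mutant against wild-type TRiC, and 7 and 1 for the totals.

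The labels give replicate numbers but no pairs. With a replicate block the calls were 325 for Ssb with puromycin (172 losses, 153 gains), 903 for TRiC against Ssb and 1223 for mutant against wild-type TRiC, with 5 ATP2 windows, and no other count moved by over 1.5 times. In the check of the pairing, bound and total libraries of the same number correlated at r = -0.047 for TRiC, 0.069 for Ssb, 0.299 and 0.233 with puromycin and 0.076 for the mutant.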

Other observations

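The mitochondrially encoded genes varied widely between libraries and were nearly empty in mutant totals. Their RPM were 37.0 and 27.3 in wild-type TRiC totals, 24.1 and 16.7 in Ssb totals, 6.75 and 8.34 in cycloheximide-free totals, and 0.184 and 0.138 in mutant totals (95% intervals 0.107 to 0.294 and 0.0819 to 0.218, counting error only). OLI1, a ring subunit of the ATP synthase, had 437 and 522 reads in wild-type TRiC totals and 3 and 1 in mutant totals. TRiC-bound libraries held 99.1 and 79.1 in wild type and 2.12 and 3.09 in the mutant, and Ssb-bound libraries held 13.3 and 14.1. With puromycin the values were 33.7 and 360 for TRiC-bound, 4.59 and 345 for TRiC total, 17.6 and 18.6 for Ssb-bound and 1.48 and 2.07 for Ssb total libraries. This count was chosen only after the fitted fold changes of these genes had been seen.

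Stop codons held 1.41% and 1.27% of reads in the cycloheximide-free libraries and 0.03% to 0.24% elsewhere.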
